A study of Homo sapiens with 4 samples.

How the data were processed

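Polyadenylated RNA was sequenced from AGS, an established human gastric adenocarcinoma cell line. The sample labels put 2 libraries in a group treated with recombinant human fibroblast growth factor 2 (FGF2, 20 ng/mL, harvested after 24 h) and 2 libraries in a group called NC, a name the labels do not spell out. The treatment text attached to the NC libraries also describes the addition of FGF2, so what the NC cells received is not given in the sources used here, and the group was taken from the titles and the treatment field. Libraries were made with an NEBNext Ultra RNA kit, per the labels' protocols. That kit does not mark the strand, so reads of overlapping genes on opposite strands cannot be told apart.

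Each library came with 1 table of 51103 genes that held the deposited raw read counts and the deposited FPKM values (counts scaled by exon length and library total). HISAT2 and HTSeq 0.13.5 with the GRCh38 genome are named in the submitters' processing notes, and the annotation release is not given in the sources used here. The FPKM values equalled the counts divided by gene length and total count. All 51103 gene identifiers are in the GENCODE v29 annotation. Of the 11923 genes with over 20 counts in every library, 99.5% had an implied length that, rounded to a whole base, equalled the merged exon length in that release. Coordinates are therefore given on GRCh38 from GENCODE v29. A total of 12 gene names had been turned into dates and were restored through their identifiers.

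The libraries of each group were compared before any averaging. In the FGF2 group, library 1 had a higher count than library 2 at 2 of 22043 genes, where 1192 would be expected of separate libraries of these depths (1105 to 1280 in 1000 simulations). In the NC group it had a higher count at 2 of 22485 genes, with 1214 expected (1122 to 1308). Among genes of 10 to 1000 counts, the chi-square per gene between the libraries of a group was 0.771 ± 0.012 (SE) for FGF2 and 0.764 ± 0.012 for NC, less than the sampling noise of separate reads. Over all genes of at least 10 counts it was 1.25 and 1.03, and for genes of at least 20000 counts 10.8 and 6.71. Library 2 thus has the counts of a library that contains the reads of library 1. The libraries of a group were therefore counted as 1 sample (n = 1 per group). This is a cautious choice, because the source of the other reads of library 2 is not known. No difference between the groups thus has a check by replicates known to be separate. Nothing in the labels says that the libraries came from separate cultures.

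The group value was taken from library 2, the deeper one. For a check within each group, the reads were parted into 2 disjoint sets, namely library 1 and library 2 less library 1, which held 13790335 and 13808282 counts for FGF2 and 14073340 and 13252368 for NC. Sets were scaled by TMM (trimmed mean of M values) over the genes kept by edgeR's filterByExpr, which left 15030 genes, 12575 of them protein-coding. Fold changes are log2 ratios of the scaled counts of both libraries 2, with 0.5 added to each count. Their 95% intervals are exact Clopper-Pearson binomial intervals of the counts. These intervals cover counting error only and are too narrow, because the chi-square per gene between the disjoint sets was between 2.08 and 2.76 in the FGF2 group for genes under 1000 counts and 43.2 for genes of at least 20000 counts. At the 1259 genes with 2 counts in FGF2 library 2, library 1 held 0, 1 or 2 of them at 478, 291 and 490 genes, where a binomial split gives 315, 629 and 314, so low counts tended to come in pairs.

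A gene was called higher or lower when both FGF2 read sets lay on the same side of both NC read sets by at least 1.5-fold, among the 11000 genes with a mean of at least 50 counts per read set. For gene lists the bound was 1.2-fold, with no count minimum. To gauge noise between read sets, the rule was also run with the 4 sets paired across groups in the other 2 ways. A gene that passes in the true grouping cannot pass in these pairings, so their low counts are partly fixed beforehand. They are no background for a difference between cultures. Counts were also simulated for FGF2 against NC over 11000 genes, with 200 changed genes. The 1.5-fold rule recovered 16% of 1.5-fold, 96% of 2-fold and 100% of 3-fold changes. It called 0 of 10800 unchanged genes, while the 1.2-fold rule called 69 of them. Unchanged genes had no simulated difference between the groups, so these calls do not cover differences between cultures. The rule, its bounds and the grouping as 1 sample were chosen after seeing the data. For a list with at least 5 genes measured, the median log2 fold change was placed among the medians of 10000 random lists of the same size matched on mean expression in 50 bins, as a description of these libraries and not a test.

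The samples, the test, the 34 gene lists and the rule for named genes were set before the data were examined. That test was edgeR's quasi-likelihood test of 2 against 2 libraries with an adjusted p under 0.05 (Benjamini-Hochberg), with camera (limma) for lists. In nested simulated libraries it called 2069 unchanged genes among 15030, against 5 for separate libraries, so its p-values were used only to choose names. Named genes were the 10 highest and 10 lowest fold changes among protein-coding genes that passed, had a mean FPKM of at least 2 in either group and did not overlap between groups. To these were added FGF2, FGFR1 to FGFR4, MYC, DUSP6, SPRY4, ETV4, ETV5 and CCND1, up to 4 members with the smallest p of each list that passed and of the ribosome lists, and up to 2 of other lists. The results of 1 gene list and of some single genes are not reported here. The alternatives were other scalings, filters, pseudocounts, tests (DESeq2, limma on FPKM and TPM), left-out libraries and a replicate block. Work was done in Python 3.11.15 and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.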

Results

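The series asked which genes of AGS gastric cancer cells respond to recombinant FGF2, a secreted growth factor that signals through FGF receptors and the ERK kinase cascade, with ribosome biogenesis named in its title. Gene counts were compared between cells treated with 20 ng/mL FGF2 for 24 h and cells labelled NC. The total was 13790335 and 27598608 counts in the FGF2 libraries and 14073340 and 27325697 counts in the NC libraries. Within each group the count of the shallower library lay at or below that of the deeper one at all but 2 genes, and the pair differed by less than the sampling noise below 1000 counts, so each pair was counted as 1 sample (n = 1 per group). The values below therefore compare 2 samples with no check by replicates known to be separate. Levels are those of the deeper library unless stated.

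The FGF2 sample had higher transcript levels of known FGF and ERK target genes and, by smaller amounts, of ribosome biogenesis factors, and lower levels of most interferon response genes measured. Of 11000 genes, 345 were at least 1.5-fold higher and 569 at least 1.5-fold lower in both read sets. The same rule took 6 and 5 genes when the read sets were paired across the groups. Genes that pass in the true grouping cannot pass in these pairings, which gauge only noise between read sets. At least 2-fold, 122 genes were higher and 179 lower, against 1 and 0 in the cross-group pairings. At the 1.2-fold bound used for gene lists, 1402 of the 11000 genes were higher and 1471 lower. The cross-group pairings took 74 and 67 genes in either direction. The shares higher and lower are only a rough baseline for the list counts, because the lists had no count minimum. Across genes, which are not independent replicates, the log2 fold changes from the 2 disjoint read sets had a Pearson r of 0.835 and a Spearman rho of 0.746. With no scaling beyond the total count the split at 1.5-fold was 264 higher and 718 lower.

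Among protein-coding genes that passed the planned test with a mean of at least 2 FPKM in either group, the highest fold change was that of MMP1, an interstitial collagenase (ENSG00000196611, chromosome 11, 102789920 to 102798160), with 264 counts in the FGF2 sample and 2 in the NC sample, a log2 fold change of 6.80 (95% counting interval 5.25 to 10.17). Low counts tended to come in pairs, so the 2 counts need not be independent fragments and that interval is too narrow. ESM1, which encodes a proteoglycan of activated endothelium, followed at 5.65 (4.55 to 7.42) and STC1, a secreted glycoprotein hormone, at 4.92 (4.21 to 5.86). The others among the 10 highest within these limits were DUSP6 (3.51), ADAMTS6 (3.46), SPRY4 (3.33), ANGPTL4 (3.28), KRTAP2-3 (3.06), TGM2 (3.06) and IL11 (2.96). IL11, a cytokine of the IL-6 family, stood at 20.2 FPKM in the FGF2 sample and 2.75 FPKM in the NC sample. DUSP6 shares 40.5% of its exon sequence with a gene on the opposite strand, so its count is uncertain. The same holds, at 10.3% to 20.8%, for FGF2, CCND1, PHLDA1, RPS25, MRPS2, HMGCS1 and PLK1, whose values follow.

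Within the same limits the lowest fold change was that of KRT4, a keratin of stratified epithelia (ENSG00000170477, chromosome 12, 52806549 to 52814551), with 6 counts in the FGF2 sample and 262 in the NC sample, a log2 fold change of -5.26 (-6.84 to -4.23). KRT4 stood at 0 FPKM in FGF2 library 1, and the other reads of library 2 gave -4.26. The chemokine scavenging receptor gene ACKR3 was at -3.92 (-5.15 to -3.03) and the endothelin gene EDN2 at -3.80 (-4.61 to -3.15). EDN2 was at -4.85 from library 1 and -3.14 from the other reads of library 2, both outside its interval. OLR1, which encodes a receptor for oxidised LDL, had 211 counts against 2533 in the NC sample (-3.51, -3.72 to -3.31). IGFBP3, which encodes a carrier of insulin-like growth factors, stood at 2.85 against 30.8 FPKM (-3.35, -3.51 to -3.19). CLIC3 (-2.98), SAMD11 (-2.90), ALPP (-2.82), COLEC12 (-2.80) and ANKRD2 (-2.80) completed the 10 lowest within these limits, and some genes outside them had lower values. ALPP shares 20.6% of its exon sequence with a gene on the opposite strand.

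**Figure D1:**
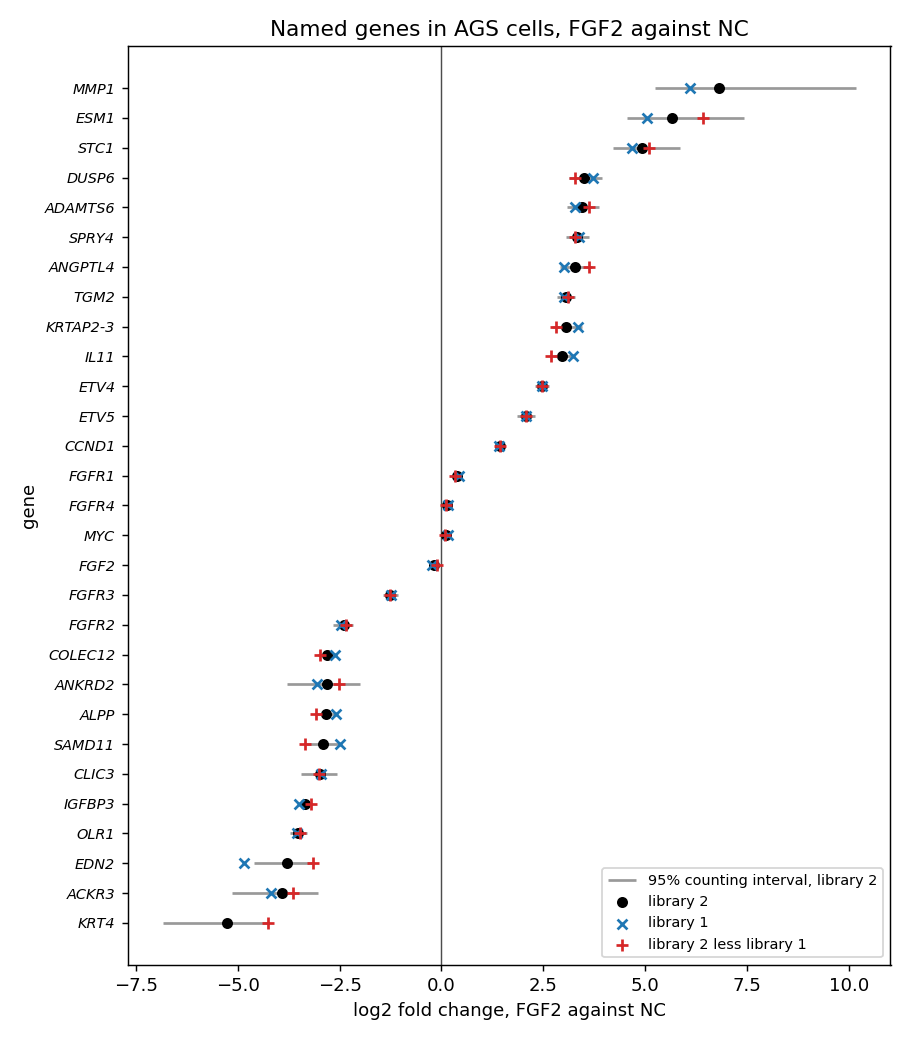
Log2 fold changes (FGF2 against NC, horizontal axis) of the 10 highest, the 10 lowest and the preset genes (vertical axis), from library 2 (black, grey bars are 95% counting intervals), from library 1 (blue crosses) and from library 2 less library 1 (red plus signs), where no count was 0. MMP1 stands at 6.80, KRT4 at -5.26 and MYC at 0.12.

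Genes that FGF and ERK signalling is known to induce were higher as a group. Of 35 measured, 27 were at least 1.2-fold higher in both read sets, 1 was lower and 7 were neither. Their median log2 fold change was 1.05, above the highest median of 10000 random lists matched on expression (0.28). Examples were the ETS factor genes ETV4 at 2.47 (2.30 to 2.64) and ETV5 at 2.07 (1.86 to 2.29), the AP-1 subunit gene FOSL1 at 1.66 (1.60 to 1.71), PHLDA1 at 2.66 (2.53 to 2.79) and the urokinase receptor gene PLAUR at 2.87 (2.68 to 3.08). CCND1, which encodes cyclin D1, stood at 125.5 FPKM against 49.5 FPKM (1.43, 1.39 to 1.47). MYC stood at 136.2 and 133.2 FPKM, a log2 fold change of 0.12 (0.08 to 0.16), and met neither bound.

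Among the receptors, FGFR2 (ENSG00000066468, chromosome 10, 121478334 to 121598458) was lower at 0.756 FPKM against 4.26 FPKM, a log2 fold change of -2.40 (-2.66 to -2.16). FGFR3 was lower at -1.25 (-1.44 to -1.06), FGFR1 higher at 0.38 (0.32 to 0.44), and FGFR4 stood at 0.14 (0.03 to 0.25), within the 1.2-fold bound. Endogenous FGF2 mRNA stood at 4.49 against 5.37 FPKM (-0.17, -0.30 to -0.04) and met neither bound. GPC1, a heparan sulfate proteoglycan gene, was lower at -0.59 (-0.63 to -0.54). Of the 13 genes of receptors, ligand and co-receptors measured, 1 was higher and 5 were lower, with a median of -0.17, at the 3.29th percentile of random lists.

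Most ribosome biogenesis factors were higher by a small amount. Of 157 measured, 108 were at least 1.2-fold higher in both read sets, 0 were lower and 49 were neither. The cross-group pairings took 1 and 1, but the 108 could not pass in them. The median log2 fold change was 0.46 (1.38-fold), against at most 0.17 in 10000 matched random lists, and 154 of the 157 values were above 0, in a range of -0.20 to 0.86. These lists follow from the title of the series, so their direction is not independent evidence. Factors of the small subunit had 43 of 58 higher (median 0.49) and those of the large subunit 44 of 66 (0.46). The snoRNP proteins had 11 of 18 higher (0.45) and the RNA polymerase I machinery 10 of 15 (0.40), with 0 lower in each of the 4 lists.

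Within these lists, EBNA1BP2 (ENSG00000117395, chromosome 1, 43164175 to 43270936), a 60S assembly factor gene, had a log2 fold change of 0.86 (0.81 to 0.91), NIP7 of 0.77 (0.69 to 0.85) and RSL1D1 of 0.63 (0.59 to 0.68). NPM1, which encodes the abundant nucleolar protein nucleophosmin, stood at 673 against 473.2 FPKM (0.59, 0.58 to 0.61). In the small subunit list RRP9 was at 0.75 (0.67 to 0.83), WDR43 at 0.68 (0.62 to 0.74), AATF at 0.67 (0.61 to 0.74) and NOL6 at 0.61 (0.55 to 0.66). The snoRNP genes NOP10 (0.70), DKC1 (0.56), NOP56 (0.53) and TCOF1 (0.53) and the polymerase subunit genes POLR1C (0.59) and POLR1B (0.53) were higher by the 1.2-fold rule. Among the 157 factors, 41 share at least 10% of exon sequence with another gene. EBNA1BP2 (18.8%), NIP7 (20.2%) and POLR1C (18.2%) do so with genes on the opposite strand. The 116 factors with less sharing had 79 higher and 0 lower, with a median of 0.45.

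Cytosolic ribosomal protein genes differed less. Of 84, 9 were at least 1.2-fold higher, 1 was lower and 74 were neither, with a median of 0.25 against 0.09 to 0.20 for the central 95% of random lists. The median was 0.31 from library 1 and 0.15 from the other reads of library 2, the latter inside that range. Among 3368 genes with a mean of at least 1000 counts, the ratio of a group's read sets correlated with gene length. Spearman rho was -0.155 in FGF2 and 0.214 in NC, and its part in that gap was not tested. RPL34 was at 0.47 (0.42 to 0.53), RPS25 at 0.42 (0.38 to 0.46) and RPL32 at 0.39 (0.35 to 0.43), and RPL5 stood at 0.30 (0.28 to 0.32), short of the rule. Their reads can be shared with processed pseudogenes, so these values are uncertain. Mitochondrial ribosomal proteins had 20 of 78 higher and 0 lower (median 0.22, MRPL3 at 0.50 and MRPS2 at 0.55). Translation initiation and elongation factors had 14 of 39 higher and 0 lower (0.32, EIF1AX at 0.47 and EIF5 at 0.43), and cytosolic aminoacyl-tRNA synthetases 10 of 20 higher and 0 lower (0.31, FARSB at 0.46). MYC target genes had 22 of 39 higher and 0 lower (0.34), among them ODC1, the first enzyme of polyamine synthesis, at 0.68 (0.65 to 0.72) and LDHA, which encodes lactate dehydrogenase A, at 0.64 (0.62 to 0.66). The 37 of these genes outside the ribosome biogenesis lists had 20 higher and 0 lower, with a median of 0.33.

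**Figure D2:**
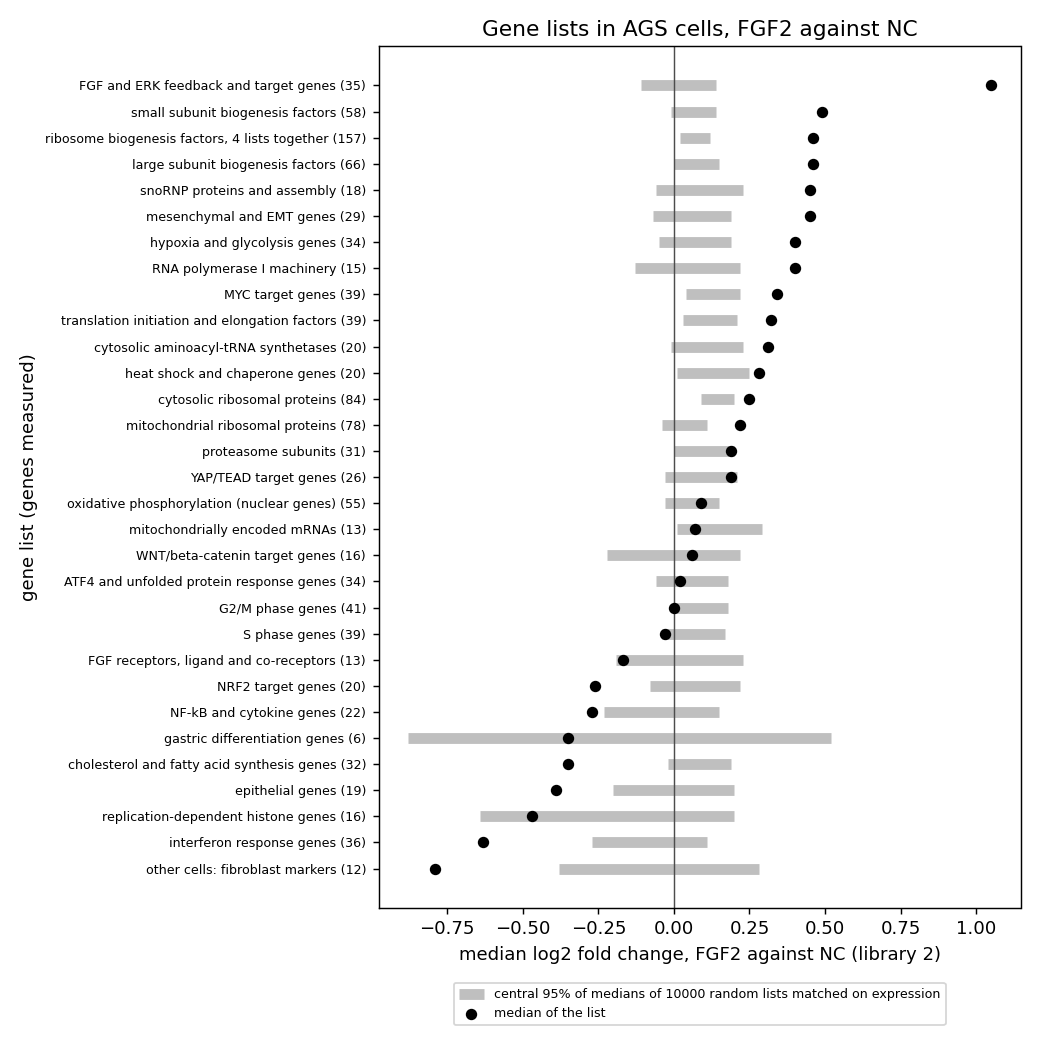
Median log2 fold change (FGF2 against NC, library 2, horizontal axis) of each preset gene list reported here with at least 5 genes measured (black points, numbers measured in brackets on the vertical axis), with the central 95% of the medians of 10000 random lists matched on expression (grey bars). The list of FGF and ERK targets stands at 1.05, the 4 ribosome biogenesis lists together at 0.46 and the interferon response list at -0.63.

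Few cell cycle genes met either bound. S phase genes had 1 of 39 higher and 3 lower (median -0.03, 3.22th percentile of random lists), and G2/M phase genes 1 of 41 higher and 2 lower (median 0.00, 2.42th percentile). E2F2 was lower at -0.93 (-1.11 to -0.75), MCM6 at -0.43 (-0.50 to -0.36) and CDC25B at -0.36 (-0.41 to -0.30), while PLK1 stood at 0.30 (0.25 to 0.35) and met neither bound. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, had 1 of 16 higher and 6 lower (-0.47, 11.54th percentile of random lists).

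Metabolic and stress lists moved apart. Hypoxia and glycolysis genes had 21 of 34 higher and 1 lower (median 0.40, above the highest random median of 0.30), with hexokinase gene HK2 at 1.21 (1.15 to 1.27), VEGFA at 1.14 (1.04 to 1.23) and the mitophagy receptor gene BNIP3 at 1.09 (1.03 to 1.15). Cholesterol and fatty acid synthesis genes had 16 of 32 lower and 1 higher (-0.35, below the lowest random median of -0.14), including TM7SF2 at -1.95 (-2.22 to -1.69), HMGCS1 at -0.98 (-1.06 to -0.90), FADS2 at -0.95 (-1.01 to -0.90) and MVD at -0.76 (-0.84 to -0.67). NRF2 target genes had 7 of 20 lower and 1 higher (-0.26), with FTL at -0.58 (-0.61 to -0.56) and TXNRD1 at -0.54 (-0.56 to -0.52).

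Heat shock and chaperone genes had 9 of 20 higher and 2 lower (0.28). HSP90AB1 was at 0.37 and HSPH1 at 0.47, whereas HSPB1, a small heat shock protein gene, was lower at -0.82 (-0.85 to -0.78). Proteasome subunits had 4 of 31 higher and 0 lower (0.19, 96.24th percentile of random lists), with PSMD2 at 0.90 (0.87 to 0.92). ATF4 and unfolded protein response genes had 3 of 34 higher and 4 lower (0.02), the higher ones including STC2 at 1.39 (1.35 to 1.44) and PPP1R15A at 0.94 (0.85 to 1.02). Nuclear genes of oxidative phosphorylation had 1 of 55 higher and 1 lower (0.09, with 0.14 from library 1 and -0.03 from the other reads of library 2). The cross-group pairings took 3 and 0 of these genes. Of 13 mitochondrially encoded mRNAs, 0 met either bound (0.07). With no scaling beyond the total count the median of the mitochondrially encoded list was -0.02 and that of the ATF4 list -0.06.

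Interferon response genes were lower. Of 36 measured, 23 were at least 1.2-fold lower and 1 was higher, with a median of -0.63, below the lowest random median of -0.53. The antiviral genes MX1 at -1.99 (-2.51 to -1.53) and OAS3 at -0.81 (-0.91 to -0.71), the immunoproteasome gene PSMB9 at -1.31 (-1.63 to -1.01) and HLA-B at -0.67 (-0.74 to -0.59) were among them, MX1 at only 45 and 190 counts. HLA-B shares 17.8% of its exon sequence with a gene on the opposite strand, and its reads can be split among the other HLA genes. NF-kB and cytokine genes had 7 of 22 lower and 3 higher (-0.27, 0.96th percentile), with the chemokine gene CCL2 at -1.87 (-2.09 to -1.67) and CSF1 at -0.79 (-0.89 to -0.68).

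Genes of epithelial and mesenchymal identity went both ways. Epithelial genes had 7 of 19 lower and 1 higher (median -0.39), with the epithelial transcription factor gene ELF3 at -3.33 (-3.91 to -2.83) and the keratin gene KRT19 higher at 0.89 (0.80 to 0.97). Mesenchymal and EMT genes had 15 of 29 higher and 6 lower (median 0.45, with a highest random median of 0.30), with MMP1 at 6.80 and PLAUR at 2.87 among the higher ones. That median was 0.41 from library 1 and 0.29 from the other reads of library 2. YAP/TEAD target genes had 8 of 26 higher and 8 lower (0.19), with IGFBP3 and TGFB2 (-1.37, -1.45 to -1.30) among the lower ones. TGFB2 shares 26.6% of its exon sequence with another gene on the same strand and is uncertain. WNT/beta-catenin target genes had 4 of 16 higher and 6 lower (0.06, and -0.03 with no scaling beyond the total), with CD44 at 1.18 (1.14 to 1.22). Of the gastric differentiation genes 6 were measured, 2 higher and 1 lower, while the cross-group pairings took 1 and 1. MUC1 was at -1.44 (-1.92 to -0.99) and MUC6 at 2.29 (1.24 to 3.67), both at under 2 FPKM. The MUC6 value rested on only 39 counts in the FGF2 sample and 8 in the NC sample.

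Markers of other cell types were also measured. Of 18 fibroblast markers, 12 were measured in these cells, and of these 8 were lower, 1 was higher and 3 were neither in the FGF2 sample, with a median of -0.79. The receptor gene PDGFRB had 1238 counts against 4095 (-1.65, -1.75 to -1.56) and the collagen gene COL5A1 at 24.2 against 57.6 FPKM (-1.16, -1.20 to -1.12). Of the endothelial markers 3 were measured, with 0 higher and 1 lower (ESAM, -0.66, -1.28 to -0.07), and the single blood and immune marker measured, CD14, stood at -0.10 (-0.71 to 0.50), with -1.32 from library 1 and 0.59 from the other reads of library 2, so no direction was detectable.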

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

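The size rule and every alternative to it, the scaling by total count and the use of disjoint read sets were chosen after seeing the data. The edgeR test planned on 2 against 2 libraries called 9376 of 15030 genes at an adjusted p under 0.05 (4679 higher, 4697 lower), but its libraries share reads, so the count has no meaning for the conditions. It called 5174 with FPKM of at least 5, 1608 with a 2-fold change as well and 6035 with DESeq2. With library 2 less library 1 in place of library 2 it called 4734. That last fit compares the conditions only if the other reads of library 2 came from a second culture, which was not decided. With no scaling beyond the total the split was 3506 higher and 6047 lower, and limma on log2(FPKM + 1) gave 2973 and 4498, on log2(TPM + 1) 2799 and 4627. Leaving out 1 library gave 7586 to 9150. A replicate block gave 9373 genes and 19 lists. The deviations of the same-numbered libraries had a correlation of -0.00695 across genes. Because library 2 has the counts of a library that contains library 1, this value cannot exclude a pairing. Camera called 19 of 32 lists with a preset correlation, 0 with an estimated one and 18 to 21 with 1 library left out.

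The counts of 345 higher and 569 lower genes became 606 and 914 with the mean of both deposited libraries, 685 and 1010 with library 2 less library 1 alone, and 587 to 672 and 882 to 945 with only 1 library per group, because fewer read sets had to pass. Lower genes numbered 303 at a mean of at least 200 counts, with fewer genes tested, 987 on log2(TPM + 1) and 1068 on log2(FPKM + 0.1), each of library 2 alone. The ribosome biogenesis median of 0.46 was 0.43 with upper-quartile scaling, 0.37 with no scaling and on log2(FPKM + 0.1), and 0.36 on log2(TPM + 1), on log2(FPKM + 1) and after quantile normalization, and 89 to 129 of 157 genes passed the 1.2-fold bound. The median of the 6 gastric differentiation genes was -0.35 and turned to 0.06 without replicate 2, and the cause was not tested. Of 1608 other values of named genes 964 stayed within the counting interval, 644 moved beyond it and 0 called values changed sign. Of 737 values of the lists other than the joint ribosome biogenesis list, 494 stayed, 242 moved and 1, just given, was a change of sign of a median further than 0.1 from 0. Medians nearer to 0 (G2/M, ATF4, WNT/beta-catenin, mitochondrially encoded and oxidative phosphorylation genes) also changed sign under some settings and are among the values that stayed or moved. Depth limits KRT4, MMP1, ESM1, STC1, EDN2, ACKR3 and ANKRD2 most among the 10 highest and 10 lowest genes, with under 20 counts in 1 group.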

Other observations

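The gene groups in this paragraph and the next were put together after the fold changes had been seen, so they describe these 2 samples and test nothing. Most genes of bone morphogenetic protein signalling were lower in the FGF2 sample. Of 14 measured, 8 were at least 1.2-fold lower and 0 higher, with a median log2 fold change of -0.76 against -0.28 to 0.20 for the central 95% of matched random lists. The inhibitor of differentiation gene ID2 was at -2.58 (95% counting interval -2.98 to -2.21), ID3 at -0.96 (-1.04 to -0.88) and ID1 at -0.54 (-0.62 to -0.47). The target gene ATOH8 was at -2.01 (-2.24 to -1.79), the feedback inhibitor gene SMAD6 at -1.15 (-1.25 to -1.04), and the ligand genes BMP5 at -1.82 and BMP4 at -1.30 (-1.42 to -1.18).

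Long noncoding transcripts that host small nucleolar RNAs in their introns were higher. Of 13 measured, 7 were at least 1.2-fold higher and 0 lower, and all 13 values were above 0. The median was 0.49 against at most 0.41 in 10000 matched random lists. It was 0.55 from library 1 and 0.41 from the other reads of library 2, the latter equal to that random value as rounded. GAS5 was at 0.68 (0.61 to 0.74), ZFAS1 at 0.59 (0.43 to 0.75) and SNHG1 at 0.44 (0.36 to 0.51), and ZFAS1 shares 26.1% of its exon sequence with a gene on the opposite strand. Genes of plasminogen activation and integrins had 11 of 14 higher and 2 lower, with a median of 1.02. ITGA2 was at 2.82 (2.33 to 3.37), ITGB5 at 1.32 (1.23 to 1.41) and PLAT at 1.02 (0.92 to 1.13), whereas ITGB4 was lower at -1.28 (-1.46 to -1.11).

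Of the tests of explanations below, the match on abundance, length and GC content was set before its result was seen, and all the others after. The first pattern is that library 1 almost never exceeded library 2 within a group. Separately sequenced libraries would give at least 1105 genes with a higher count in library 1, and the larger of the 2 groups' counts was 2. If library 2 holds the reads of library 1, the chi-square per gene should lie under 1 where reads are few, and for genes of 10 to 1000 counts the larger value was 0.771. Over all genes of at least 10 counts it was 1.25 and 1.03, so the chi-square prediction held for the less abundant genes only. Library 1 was at or below library 2 at all but 2 of 22043 FGF2 and 2 of 22485 NC genes, whatever their abundance. Plain further sequencing of the same library would give a chi-square between the disjoint sets that does not rise with counts. In the FGF2 group it rose from 2.08 at 10 to 50 counts to 43.2 at 20000 counts or more. In the NC group it rose from 2.31 to 32.2, which with the FGF2 values argues against that source alone. Whether the other reads of library 2 came from a second culture or from another preparation of the first was not decided by these tables.

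The second pattern is the higher level of ribosome biogenesis factors. A trend with abundance, gene length and GC content is argued against, since the highest median among 10000 lists matched on all 3 was 0.18 and that of the factors was 0.46. Scaling is argued against as the whole source, as the lowest median under the 3 other scalings was 0.37. The median was 0.46 from library 1 and 0.46 from the other reads of library 2. If those reads came from another preparation or culture, the equal medians argue against a difference made in 1 preparation only. A response to FGF2 stays open as a hypothesis, untested. With 1 sample counted per group, a difference between cultures, or in preparation between the groups, is not excluded.

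The third pattern is the lower level of most fibroblast markers measured in the FGF2 sample. Fibroblasts mixed into the NC culture would bring their other abundant transcripts. The highest of COL1A2, COL3A1, DCN and LUM in the NC sample was 0.736 FPKM, whereas COL1A1 stood at 103.8 FPKM there and 59.5 FPKM in the FGF2 sample. COL1A2 had 0 counts in both. The other 3 went the way of such a mixture at low levels, COL3A1 with 6 against 137 counts, DCN with 0 against 8 and LUM with 0 against 12, so a trace of it stays open for them, while it is argued against for COL1A1. A change of these genes within AGS cells stays open as a hypothesis, and no biological explanation was tested for it.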
